A study of Mus musculus with 13 samples.

How the data were processed

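Dissected embryonic mouse cortex was dissociated with papain and made into single-cell RNA libraries with the 10x Genomics 3' v3.1 chemistry, per the labels. There were 13 libraries from 4 groups: E12.5 control (n = 3), E12.5 BRN1/2 conditional knockout (cKO, n = 3), E14.5 control (n = 3) and E14.5 cKO (n = 4). BRN1 and BRN2 are the proteins of Pou3f3 and Pou3f2. The labels also give each embryo's sex and collection date. The recombinase, the deleted interval and the control genotypes are not given in the sources used here. The library numbers used here follow the order of the deposited samples within a group and carry no pairing.

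The deposited matrices hold counts, raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 6.0.1 per the file headers. The other deposited files hold the cell barcodes and the list of 32285 features. The submitters' processing notes name the mm10 build (GRCm38), and the annotation release is not given in the sources used here. Gene positions were taken from GENCODE vM21. A library held 9611 to 15135 barcodes and 119 to 176 M UMIs (M, 1e6).

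Barcodes with fewer than 1000 detected genes or more than 10% mitochondrial UMIs were removed. Scrublet scores as implemented in scanpy 1.11.5 were computed per library, and the highest-scoring barcodes were removed at 0.8% per 1000 barcodes. Between 6791 and 10732 cells per library remained, 115621 in all, with medians of 8766 to 18482 UMIs and 2983 to 4410 genes. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without Pou3f2, Pou3f3, Xist, Tsix, chromosome Y and mitochondrial genes, gave 30 principal components, a graph of 15 neighbours and Leiden clusters at a resolution of 1.5 (Python 3.11.15, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, seed 0). No integration across libraries was used. Clusters were named from marker lists of cell types: a name needed at least 3 markers detected in 10% of the cluster's cells, and the 10 most specific genes of each cluster were checked. Names end in "-like" because they rest on these markers alone. Clusters with too few markers, or with more markers of another type than of their own among those genes, stayed unnamed, counted in the total of the shares and were not tested.

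UMIs were summed per library and class where a library had at least 20 cells of it, and libraries, not cells, were the replicates. Radial glia-like sums held 12.1 to 57.1 M UMIs, intermediate progenitor-like sums 1.60 to 14.6 M, and excitatory neuron-like sums 4.60 to 78.7 M. Sums were tested with edgeR 4.0.16 (R 4.3.3; TMM factors, filterByExpr, glmQLFit with robust = TRUE, glmQLFTest) with 1 mean per group over all 13 libraries, which left 9 residual degrees of freedom. Tests were two-sided, and adjusted p values are Benjamini-Hochberg values over all genes tested in a contrast, called at 0.05. Contrasts were cKO against control in 3 classes at each of 2 stages, the difference of the stage effects in each class, and E14.5 against E12.5 in control radial glia-like cells. Levels are counts per M UMIs of the class sum (CPM), means carry the SD over libraries, and log2 fold changes carry an approximate standard error (SE). This SE is the size of the change divided by the square root of its F statistic, and is rough where 1 group lies near 0 counts. Intervals and floors (3 counts) cover counting error only.

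Of 27 gene lists, those with at least 5 measured members in a class were tested in each contrast with camera (limma 3.58.1, preset correlation 0.01, log CPM with a prior count of 2, Benjamini-Hochberg over lists), and again with an estimated correlation. The 28 list calls of the 6 contrasts of cKO against control were all lost with the estimated correlation. The members that passed were also counted with p values adjusted over the list alone. Class shares are percentages of all kept cells of a library. They were compared by exact two-sided permutation of libraries within a stage, and over both stages by permuting genotype within stage (700 arrangements). With 3 libraries against 3 the smallest exact p is 0.1, and with 3 against 4 it is 0.0286.

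The named genes follow a rule. In each contrast of cKO against control these are the 8 largest rises and the 8 largest falls among called genes with an average log2 CPM of at least 4 whose cKO libraries all lay beyond all controls of the stage. The rule left out Pou3f2, Pou3f3, Xist, Tsix, chromosome Y genes and unnamed gene models, which still count in totals. For the stage contrast and the differences of stage effects it takes 5 per direction without the condition on overlap. From each list that was called, or that had at least 3 members past the threshold, up to 4 passing members with the smallest p are added, and the POU class III genes are always given. The groups, tests, marker and gene lists, naming rule and cell filters were chosen before the data were examined.

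The fit and lists were tested on data simulated from these counts with 200 genes changed per contrast. At E14.5 the fit called 71.6%, 82.1% and 68.2% of 2-fold changes in radial glia-like, intermediate progenitor-like and excitatory neuron-like sums. At E12.5 these were 64.2%, 60.0% and 46.2%. False calls made up 1.45% to 7.14% of calls, which need not hold for real libraries.

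Alternatives chosen at the start were DESeq2 1.42.0, RLE size factors, no filter on low counts, a collection date term, a sex term, only the libraries of the stage, an estimated correlation for lists, doublets kept, at least 2000 genes per cell, each stage clustered on its own, clustering without the called genes, cell counts tested with edgeR, shares within date or of the 3 main classes, and each library left out. A Leiden resolution of 1 and leaving out the first or the last collection date were added after the data were seen. Unspliced reads, cell trajectories and the unnamed clusters were not analysed here.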

Results

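The series compares the cortex of BRN1/2 cKO mouse embryos with that of controls, at E12.5 and at E14.5, by single-cell RNA sequencing. Its description names the controls as littermates, but no control shares the collection date of 2 E14.5 cKO embryos. There were 3 E12.5 control, 3 E12.5 cKO, 3 E14.5 control and 4 E14.5 cKO embryos, 1 library each. E12.5 control libraries 1 to 3 held 129, 176 and 120.0 M UMIs, and E12.5 cKO libraries 147, 138 and 149.8 M. E14.5 control libraries held 119, 169 and 155 M UMIs, and E14.5 cKO libraries 149, 149, 135 and 128 M. Embryos were collected on 3 dates: the first gave 1 library of every group, the second 2 libraries of every group but E14.5 cKO, which had 1, and the last 2 E14.5 cKO libraries and nothing else. In the library labelled E12.5 control 2, 3430 barcodes had too few genes and 2007 too many mitochondrial UMIs, and 2216 of its 6791 kept cells were meningeal fibroblast-like.

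The first comparison asked how the targeted genes themselves were transcribed. Pou3f2 (ENSMUSG00000095139; chromosome 4, 22482780 to 22488366, GRCm38) encodes BRN2, and Pou3f3 (ENSMUSG00000045515; chromosome 1, 42695768 to 42703176) encodes BRN1, both POU domain transcription factors read from a single exon. In E14.5 radial glia-like cells Pou3f2 fell from 42.9 ± 19.8 CPM in controls (SD, n = 3) to 2.90 ± 0.361 CPM in cKO libraries (n = 4), a log2 fold change of -3.86 ± 1.00 (adjusted p = 0.0455, range 0.000375 to 0.289 over the alternatives). At E12.5 it measured 13.7 ± 19.0 CPM in controls and 1.82 ± 1.29 CPM in cKO libraries (n = 3 each; log2 -3.26 ± 1.20, adjusted p = 0.374). The 3 E12.5 controls lay at 35.5, 0.464 and 5.09 CPM. The value of 0.464 (95% Poisson interval 0.265 to 0.754) belongs to the library labelled E12.5 control 2 and lies below all 3 cKO libraries of its stage. The lowest of these, at 0.674 CPM, lies within that interval. E12.5 control 3, the other E12.5 control of the second date, had 5.09 CPM. The low value thus questions the label of that library but does not settle its genotype. Within dates the E12.5 difference was -4.53 on the first date (1 against 1) and -0.11 on the second (2 against 2), and the E14.5 difference was -3.01 (1 against 1) and -4.03 (2 controls against 1 cKO). The E14.5 call was lost without any 1 of 11 libraries, all but E12.5 control 1 and the library labelled E12.5 control 2, with adjusted p between 0.00579 and 0.137 over the 13 omissions.

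Pou3f3 tags showed no change called by edgeR over all 13 libraries. In radial glia-like cells they measured 289 ± 20.1 CPM in E14.5 controls and 413 ± 12.1 CPM in E14.5 cKO libraries (log2 0.52 ± 0.26, adjusted p = 0.272), and 194 ± 64.5 against 262 ± 102 CPM at E12.5 (log2 0.39 ± 0.27, adjusted p = 0.689). The E14.5 groups did not overlap (chance 2 of 35 arrangements), and a fit of the E14.5 libraries alone called the gene at 0.52 (adjusted p = 0.00153), as did leaving out the first date at 0.47 (adjusted p = 0.00617; range 0.00153 to 0.540 over the alternatives). Within dates the differences were 0.43 and 0.34 at E12.5 and 0.61 and 0.54 at E14.5. The 3' UTR that such tags read is 4537 bp long, and the deleted interval is not given in the sources used here. Tags outside the deleted part check nothing about the deletion. Meningeal fibroblast-like cells, taken as background, held 6.97 ± 5.82 CPM of Pou3f3 in E12.5 controls (n = 2). They were not among the classes set as background at the start, which were microglia, endothelial and erythroid cells. Erythroid-like cells held 17.6 ± 20.1 CPM in E12.5 controls (n = 2). Microglia- or macrophage-like cells held 9.23 CPM in E12.5 controls (n = 1) and 48.9 ± 25.4 CPM in E14.5 cKO libraries (n = 3). The Cajal-Retzius-like values given next do not stand clear of that background. In E14.5 Cajal-Retzius-like cells, chosen after their values were seen, Pou3f3 stood at 43.5 ± 4.68 CPM in controls and 22.1 ± 6.06 CPM in cKO libraries (log2 -0.95 ± 0.25, unadjusted p = 0.00155, not called by edgeR).

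Noncoding genes beside Pou3f3, chosen after their values were seen, differed strongly at E14.5. Gm20646 (ENSMUSG00000093436; chromosome 1, 42694925 to 42744791), which spans Pou3f3 on the same strand, rose from 1.70 ± 0.184 to 58.3 ± 2.09 CPM in radial glia-like cells (log2 5.09 ± 0.61, adjusted p = 0.000953). Dalir (ENSMUSG00000099784; 42750712 to 42752881) rose from 0.0659 ± 0.0632 to 9.41 ± 0.197 CPM (log2 7.06 ± 0.95, adjusted p = 0.00149). The antisense gene Pantr2 (ENSMUSG00000097063; 42707061 to 42713454) fell from 5.17 ± 0.401 to 0.486 ± 0.117 CPM (log2 -3.40 ± 0.46, adjusted p = 0.000942), and Pantr1 (ENSMUSG00000060424; 42590782 to 42694842) measured -0.97 ± 0.29 (adjusted p = 0.0718). In intermediate progenitor-like cells Gm20646 rose by 5.16 ± 0.53 and Dalir by 6.05 ± 0.48, and in excitatory neuron-like cells by 4.40 ± 0.49 and 6.94 ± 0.81. At E12.5 Gm20646 rose in radial glia-like cells by 3.40 ± 0.57 (adjusted p = 0.0444, range 1.23e-05 to 0.443; lost without any 1 library but the library labelled E12.5 control 2). Its E12.5 control values were 1.93, 8.21 and 1.09 CPM, the highest in the library labelled E12.5 control 2, against 28.3 to 54.1 CPM in cKO libraries. In interneuron-like cells, which arise outside the cortex, Gm20646 measured 3.16 ± 0.580 CPM in E14.5 controls and 5.32 ± 1.36 CPM in E14.5 cKO libraries.

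**Figure D1:**
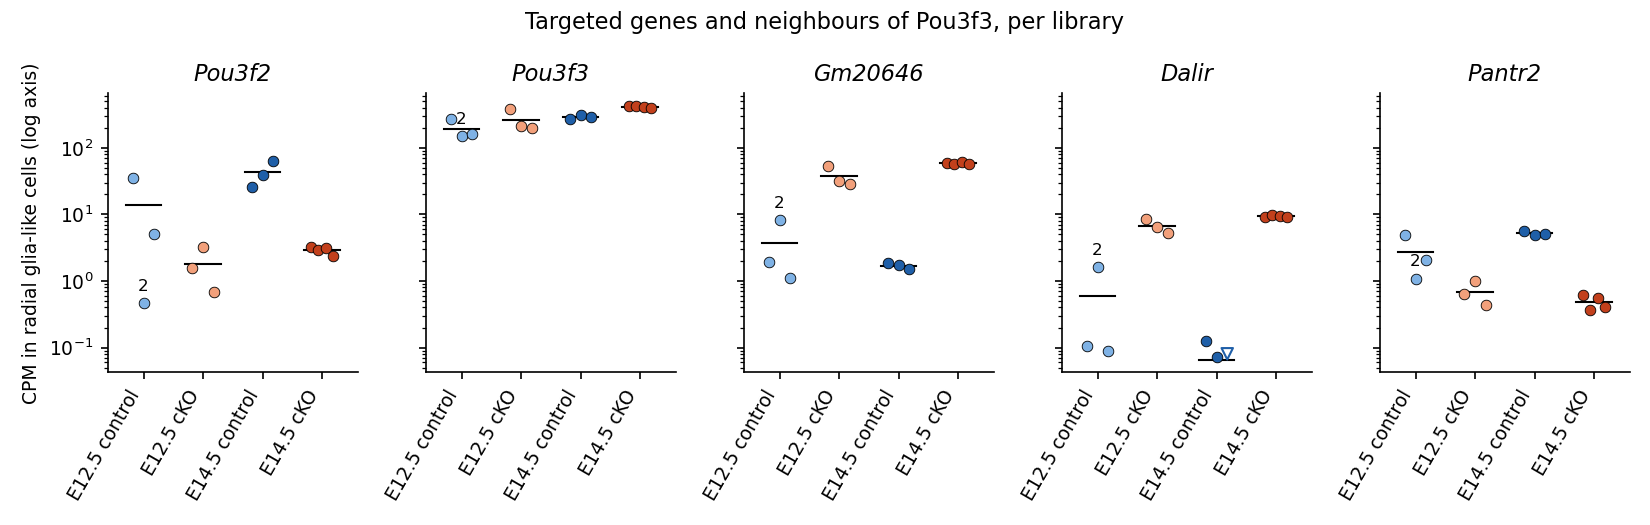
CPM of Pou3f2, Pou3f3, Gm20646, Dalir and Pantr2 in radial glia-like cells on a log axis, with 1 point per library, bars at group means, open triangles for a count of 0 drawn at 3 counts, and "2" marking the library labelled E12.5 control 2. Gm20646 lies at 28.3 to 54.1 CPM in E12.5 cKO libraries and at most at 8.21 CPM in E12.5 controls.

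The other POU class III genes were read next. Pou3f1 (ENSMUSG00000090125; chromosome 4, 124656807 to 124660655), a close relative of the targeted pair, fell at E14.5 by 3.67 ± 0.39 on the log2 scale in radial glia-like cells (adjusted p = 0.000255), by 3.82 ± 0.42 in intermediate progenitor-like cells (adjusted p = 0.000358) and by 2.77 ± 0.14 in excitatory neuron-like cells (adjusted p = 5.95e-07). Pou3f4 (ENSMUSG00000056854; chromosome X, 110814280 to 110817207) fell by 1.53 ± 0.24 in radial glia-like cells (adjusted p = 0.00219) and by 0.97 ± 0.26 in intermediate progenitor-like cells (adjusted p = 0.0286, lost without any 1 of 6 E14.5 libraries, all but cKO 1, with a range of 0.00625 to 0.272 over the alternatives), and measured -1.31 ± 0.35 in excitatory neuron-like cells (adjusted p = 0.0839). Pou3f2 also fell in the other classes at E14.5, by 3.91 ± 0.83 in intermediate progenitor-like cells (adjusted p = 0.0148; 0.0569 without control 3) and by 2.99 ± 0.50 in excitatory neuron-like cells (adjusted p = 0.0114; 0.0522 without control 2 and 0.0635 without control 3). Pou3f3 measured 0.29 in intermediate progenitor-like cells (adjusted p = 0.303) and 0.56 ± 0.16 in excitatory neuron-like cells (adjusted p = 0.0927). At E12.5 none of the 4 genes was called in the 3 classes by edgeR. Pou3f1 measured -0.65 ± 0.42 in radial glia-like, -1.47 in intermediate progenitor-like and -0.62 ± 0.15 in excitatory neuron-like cells, with adjusted p = 0.654, 0.513 and 0.272. Pou3f4 measured -0.45, 0.26 and -0.42. Pou3f2 measured -2.02 in E12.5 intermediate progenitor-like and -1.30 in E12.5 excitatory neuron-like cells, and Pou3f3 0.07 and 0.11.

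The next comparison asked which genes differ in radial glia-like cells, the cortical stem cells, at E12.5 (3 cKO against 3 control libraries, including the library labelled E12.5 control 2). Gpc1 (ENSMUSG00000034220; chromosome 1, 92831645 to 92860779), a heparan sulfate proteoglycan that binds growth factors, fell by 1.23 ± 0.12 on the log2 scale (adjusted p = 0.000911). Bhlhe22, a transcription factor of postmitotic cortical neurons, fell by 1.97 ± 0.29 (adjusted p = 0.0117), and Rnd2, needed for migration of newborn neurons, by 1.20 ± 0.16 (adjusted p = 0.00679). Masp1 fell by 0.98 ± 0.16, Zfp428 by 0.84 ± 0.11, Nr4a2, an orphan nuclear receptor, by 0.57 ± 0.09, and Celsr2, a planar cell polarity cadherin, by 0.47 ± 0.07. Palld, an actin crosslinker, rose by 0.58 ± 0.08 (adjusted p = 0.00806), as did Nav1, a microtubule-binding protein (0.60 ± 0.10), and Gli3, a transcription factor of dorsal telencephalic patterning (0.38 ± 0.07).

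Among the gene lists, 42 S phase genes moved down at E12.5 (median log2 -0.12, adjusted p = 9.67e-08, but adjusted p = 0.527 with an estimated correlation), with 0 members called over all genes and 5 lower when adjusted over the list alone. So did 52 G2/M phase genes (median -0.13, adjusted p = 1.12e-08, adjusted p = 0.527 with an estimated correlation), with 0 members called either way and a median of 0.10 when clustered without the called genes. FGF and BMP signalling moved up (24 members, median 0.13, adjusted p = 0.00505; adjusted p = 0.527 with an estimated correlation), with 0 members called either way. Of 18 deep-layer neuron genes 3 fell, including Pcp4, a calmodulin-binding peptide (-1.55 ± 0.28), and adjusted over the list alone 4 were lower and 1 higher; as a list they were not called (adjusted p = 0.199). Markers of other cell types moved with the genotype in the same sums. The interneuron list (13 members, median 1.06) was higher with adjusted p = 0.00505, and with adjusted p = 0.527 with an estimated correlation. The blood list (8 members, median -0.90) was lower with adjusted p = 0.0451, and with adjusted p = 0.570 with an estimated correlation. Both had 0 members called either way. The interneuron call was lost without E12.5 cKO 2 (adjusted p = 0.270), and the blood call without E12.5 cKO 1 (0.559), without E14.5 cKO 2 (0.0540) and without the library labelled E12.5 control 2 (0.474).

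In all 46 of 15466 genes changed at E12.5 in radial glia-like cells, 14 higher and 32 lower, and 1612 had an unadjusted p under 0.05. All 46 showed no overlap between the groups, as did 14.8% of the genes tested, where chance gives 10%. The count fell to 7 without cKO 1, 15 without control 3, 28 without cKO 2 and 29 without E14.5 control 2, and rose to 158 without the library labelled E12.5 control 2. With collection date as a term it was 101, of which 44 were among the 46. Fitting only the libraries of the stage left almost no calls, and DESeq2 called many more, as given below. Of the 14 named genes called, Gpc1 stayed called without any 1 library, and 12 were lost without cKO 1 (Palld at adjusted p = 0.0505, Rnd2 at 0.0505, Bhlhe22 at 0.0540).

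At E14.5 the same question was asked of radial glia-like cells with 4 cKO and 3 control libraries. Epha7 (ENSMUSG00000028289; chromosome 4, 28813131 to 28967499), an ephrin receptor, fell by 2.14 ± 0.17 on the log2 scale (adjusted p = 3.36e-05), Gpc1 by 1.89 ± 0.11 (adjusted p = 2.75e-06) and Pcdh10, a protocadherin, by 2.37 ± 0.24 (adjusted p = 0.000223). Mir124-2hg, host of the neuronal microRNA miR-124, fell by 2.70 ± 0.44, and Gria2, an AMPA receptor subunit, by 2.63 ± 0.35. Of 24 neuronal differentiation genes 2 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.23, list adjusted p = 0.513). Igfbp5 (ENSMUSG00000026185; chromosome 1, 72857932 to 72874884), which binds insulin-like growth factors, rose by 2.89 ± 0.26 (adjusted p = 0.00013). Ly6h rose by 2.00 ± 0.28, Adamts18 by 1.87 ± 0.26, Nav2 by 1.82 ± 0.27 and Wls, which carries Wnt proteins to the cell surface, by 1.67 ± 0.27. The cells of the 2 groups lay mostly in different clusters: clusters 13 and 23 held 43.4% and 28.4% of radial glia-like cells of cKO libraries on average and 1.49% and 6.91% of those of controls, whose most frequent clusters were 18 (19.2%), 8 (18.7%) and 12 (17.0%).

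Of 19 cyclins and cell cycle inhibitors 2 rose and 1 fell in E14.5 radial glia-like cells, without a list call (adjusted p = 0.756). Of 42 S phase genes 8 fell, 11 when adjusted over the list alone (median -0.18, adjusted p = 1.76e-08; adjusted p = 0.653 with an estimated correlation), such as Usp1, a deubiquitinase of DNA repair (-0.32 ± 0.07; adjusted p = 0.0650 without control 1), and Rrm1, the large subunit of ribonucleotide reductase (-0.29 ± 0.06; 0.0636 without control 1 and 0.0733 without control 2). Of 52 G2/M phase genes 12 fell, 17 adjusted over the list alone (median -0.15, adjusted p = 6.74e-09; adjusted p = 0.514 with an estimated correlation), such as Bub1 of the spindle checkpoint (-0.31 ± 0.06; 0.0526 without control 2). Of 28 primary microcephaly genes 2 fell, 2 adjusted over the list alone (median -0.19, adjusted p = 1.81e-07; adjusted p = 0.514 with an estimated correlation). Those were Cit and Cenpe, of cytokinesis and chromosome alignment, by 0.25 and 0.21. Both calls were lost without any 1 of E14.5 controls 1, 2 and 3 and cKO 3 and 4 (adjusted p 0.0572 without control 1 to 0.127 without control 2 for Cit, and 0.0507 without cKO 4 to 0.142 without control 2 for Cenpe). Cenpe was also lost without E14.5 cKO 2 (0.0807), E12.5 cKO 2 (0.0625) or E12.5 control 3 (0.0508). At a clustering resolution of 1 the G2/M median was 0.0171 and Cenpe measured 0.0161. Over the alternatives the adjusted p of the S phase list ran from 7.41e-16 to 0.653. The S phase, G2/M and microcephaly lists were also lower in E14.5 interneuron-like cells, as given below.

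Other lists with called members were not called as lists. Of 22 radial glia identity genes 4 fell and 3 rose (4 and 4 adjusted over the list alone): Nes, an intermediate filament of neural progenitors, fell by 1.10 ± 0.12 (adjusted p = 0.00014) and Sox2, a stem cell transcription factor, by 0.46 ± 0.08, while Gli3 rose by 0.34 ± 0.06. Of 24 Notch pathway genes 2 fell, the ligands Dll1 (-0.83 ± 0.15, but a log2 fold change of 0.0385 with each stage clustered on its own) and Dll3 (-1.48 ± 0.28), and 1 rose (2 and 2 adjusted over the list alone; the mean is negative and the median positive). Of 18 intermediate progenitor program genes 3 fell and 0 rose, with the same counts adjusted over the list alone, and the proneural factor Neurog1 fell by 2.69 ± 0.47 (adjusted p = 0.00493). Cluster 8, with Neurog2 and Gadd45g among its top genes, held 18.7% of control and 0.708% of cKO radial glia-like cells on average at E14.5. Its part in the falls of Neurog1, Dll1 and Dll3 was not tested. Of 19 p53 response genes 3 rose (3 higher and 1 lower adjusted over the list alone), among them Bbc3, a proapoptotic BH3 protein (0.97 ± 0.14), and Phlda3 (0.65 ± 0.13). Of 24 FGF and BMP signalling genes 3 rose, 5 adjusted over the list alone, among them Bmp7 (1.40 ± 0.27) and Fgfr1 (0.64 ± 0.13). The adjusted p of these 5 lists were 0.532, 0.796, 0.306, 0.306 and 0.306. Among 18 deep-layer genes Fezf2, a selector of subcerebral neurons, rose by 0.50 ± 0.08 and Bhlhe22 fell by 1.58 ± 0.23. Among 28 Wnt pathway genes Fzd9 rose by 0.53 and Wnt7a fell by 1.66 ± 0.32; their lists' adjusted p were 0.340 and 0.756.

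Over all genes, 1209 of 15466 changed in E14.5 radial glia-like cells, 705 higher and 504 lower. Groups of 1195 of them did not overlap, and 23.0% of the genes tested showed none, where chance gives 2 of 35 arrangements. Without control 1, 2 or 3 the count was 750, 503 or 604, and without cKO 3 or 4 it was 713 or 772. With collection date as a term it was 783, of which 668 were among the 1209, and without the last date 426, of which 402 were. Of 65 named genes called, Pou3f2 not counted, 36 stayed called without any 1 library.

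Whether the E12.5 and E14.5 effects were alike in radial glia-like cells was tested directly. Of the 46 genes called at E12.5, 43 were called at E14.5 in the same direction, 14 higher and 29 lower, against 1.68 for independent lists, and 0 in the opposite direction. The overlap was 6 without E12.5 cKO 1 and 127 without the library labelled E12.5 control 2. It also moved strongly with DESeq2 and with only the libraries of the stage, as given below. Across genes, which are not independent replicates, the log2 fold changes of the stages had Pearson's r of 0.560. Of the genes called at E14.5, 89.7% had the same sign at E12.5, which is measured on genes selected at E14.5 and does not compare the sizes of the effects. A difference between the stage effects was called for 2 genes, and 1299 had an unadjusted p under 0.05. Cadm1 (ENSMUSG00000032076; chromosome 9, 47530173 to 47857637), a synaptic adhesion protein, rose more at E14.5 (difference 0.68 ± 0.09, adjusted p = 0.0244). Prrx2, a homeobox gene chosen after its values were seen, differed by 1.52 (adjusted p = 0.0244). Counts of such genes moved with single libraries: they rose to 33, 12 and 4 without E12.5 control 1, E12.5 cKO 1 and E14.5 cKO 1, fell to 1 without E14.5 control 2, and fell to 0 without each of the other libraries but E14.5 control 1.

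**Figure D2:**
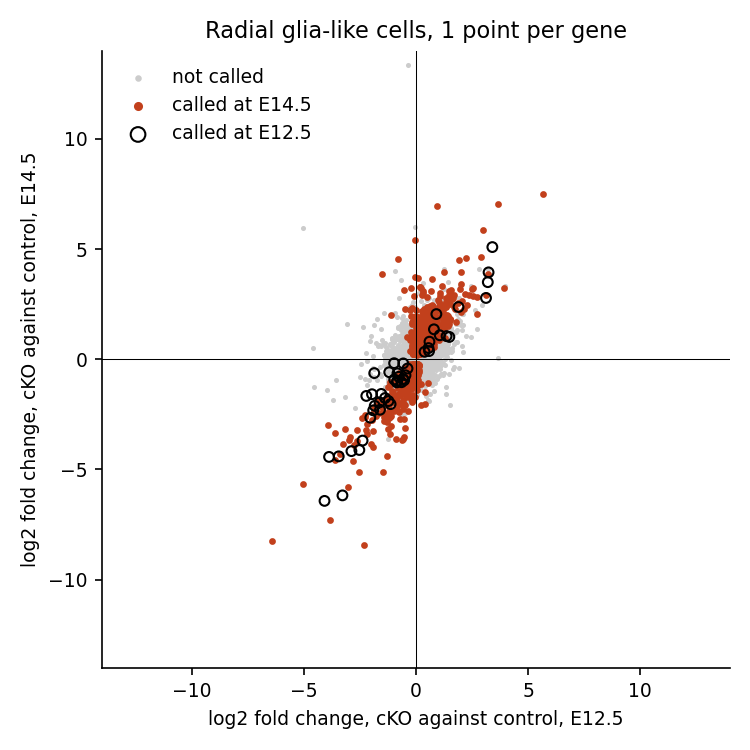
Log2 fold change of cKO over control in radial glia-like cells at E12.5 (horizontal axis) and E14.5 (vertical axis), 1 point per gene; red points were called at E14.5, black circles at E12.5 and grey points at neither. Across genes Pearson's r is 0.560, and 43 of the 46 genes called at E12.5 were also called at E14.5.

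Intermediate progenitor-like cells, the transit-amplifying neurogenic progenitors, were compared next. At E14.5 Dll3, a Notch ligand of committed progenitors (ENSMUSG00000003436; chromosome 7, 28293553 to 28302238), fell by 3.54 ± 0.42 on the log2 scale (adjusted p = 0.000407), Rnd2 by 2.58 ± 0.27 (adjusted p = 0.000202), and Tet2, a DNA demethylase (ENSMUSG00000040943; chromosome 3, 133463679 to 133545139), by 2.42 ± 0.24 (adjusted p = 4.51e-05). The differentiation factor Nhlh1 fell by 2.49 ± 0.37, Tmem108 by 3.57 ± 0.35 and Ube2ql1 by 3.68 ± 0.50. Among the genes that rose, Dbx1, a homeobox gene of the pallial borders (ENSMUSG00000030507; chromosome 7, 49631499 to 49636849), measured 5.14 ± 0.80 (adjusted p = 0.0029), Igfbp5 4.86 ± 0.60, Chodl 3.82 ± 0.40, Ly6h 3.00 ± 0.43 and Sparc, a matricellular glycoprotein, 2.55 ± 0.25 (adjusted p = 5.08e-05). Cluster 7 held 81.1% of cKO cells of this class on average and cluster 6 held 65.7% of control cells. Cluster 38, with Eomes and Neurod1 among its top genes, was placed in the excitatory neuron-like class. It held 16.5% of cKO and 1.72% of control cells of that class on average. The genotypes thus filled the intermediate progenitor-like class from different clusters. How far this accounts for the changes in this class was not tested.

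Of 42 S phase genes 22 fell in E14.5 intermediate progenitor-like cells, 30 adjusted over the list alone (median -0.46, adjusted p = 7.4e-14; adjusted p = 0.195 with an estimated correlation), such as Rrm1 (-0.67 ± 0.11). Of 52 G2/M phase genes 11 fell, 19 adjusted over the list alone (median -0.40, adjusted p = 7.61e-12; adjusted p = 0.343 with an estimated correlation), such as Kif11, a mitotic kinesin (-0.72 ± 0.14), and Mki67 (-0.59 ± 0.12). Of 28 primary microcephaly genes 6 fell, 6 adjusted over the list alone (median -0.33, adjusted p = 1.89e-06; adjusted p = 0.195 with an estimated correlation). Of these, Ncapd3 (adjusted p = 0.0663), Cenpj (0.0711), Cit (0.0607) and Knl1 (0.126) were lost without E14.5 control 1. Cit was also lost without control 3 (0.0636), and Knl1 without cKO 3 (0.0626) and cKO 4 (0.0525). Of 24 neuronal migration genes 9 fell and 2 rose, 10 and 2 adjusted over the list alone (median -0.51, adjusted p = 0.000131; adjusted p = 0.164 with an estimated correlation). Of 20 area patterning genes 7 fell and 1 rose, 9 and 2 adjusted over the list alone (median -0.32, adjusted p = 0.00163; adjusted p = 0.195 with an estimated correlation), with Epha7 at -2.20 ± 0.18. Of 24 neuronal differentiation genes 4 fell and 2 rose, 12 and 3 adjusted over the list alone (median -0.49, adjusted p = 0.0165; adjusted p = 0.195 with an estimated correlation), and Sox11, a SoxC factor of newborn neurons, fell by 0.94 ± 0.12. That call was lost without E14.5 cKO 2 (adjusted p = 0.0536).

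Lists of radial glia and of signalling moved up in the same class, which held different clusters in the 2 genotypes. Of 24 late radial glia genes 8 rose, and 10 were higher and 1 lower adjusted over the list alone (median 0.63, adjusted p = 6.11e-05; adjusted p = 0.195 with an estimated correlation), such as Sox9, a glial determinant (0.87), and Sparcl1 (2.79). Of 24 Notch pathway genes 3 rose and 1 fell, 9 and 1 adjusted over the list alone (median 0.19, adjusted p = 0.0209; adjusted p = 0.195 with an estimated correlation), with the effector Hes5 at 1.05 ± 0.16 and the receptor Notch2 at 1.14 ± 0.23. Of 19 FGF and BMP signalling genes 4 rose, 5 adjusted over the list alone (median 0.48, adjusted p = 0.00172; adjusted p = 0.195 with an estimated correlation), such as Fgfr1 (1.25 ± 0.16). Of 18 glycolysis and hypoxia genes 5 rose, 5 adjusted over the list alone (median 0.21, adjusted p = 0.00163; adjusted p = 0.281 with an estimated correlation), such as the glycolytic enzyme Tpi1 (0.86 ± 0.13). Of 10 Shh pathway genes 2 rose, 2 adjusted over the list alone (median 0.42, adjusted p = 0.00936; adjusted p = 0.195 with an estimated correlation). Of 22 radial glia identity genes 6 rose and 2 fell, 8 and 2 adjusted over the list alone, without a list call (adjusted p = 0.0632), and Vim, an intermediate filament, rose by 1.03 ± 0.19. The Notch call was lost without cKO 2 (adjusted p = 0.0501) and without control 3 (0.0636). The Shh call was lost without E12.5 cKO 1 (0.0556), E14.5 control 1 (0.0502), the library labelled E12.5 control 2 (0.0538) and E12.5 control 3 (0.0578). With each stage clustered on its own the medians of the neuronal differentiation, Shh and glycolysis lists were 0.34, -0.04 and -0.12, and Hes5 and Notch2 measured -0.01 and -0.28.

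In total 1572 of 12440 genes changed in E14.5 intermediate progenitor-like cells, 891 higher and 681 lower. Groups of 1507 of them did not overlap, as for 27.8% of the genes tested, where chance gives 2 of 35 arrangements. The count was 870, 874, 1007 and 1005 without control 1, control 3, cKO 3 and cKO 4. It was 976 with a date term (860 among the 1572) and 650 without the last date (602 among them). Of 82 named genes called 60 stayed called without any 1 library.

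At E12.5 few genes changed in intermediate progenitor-like cells. Emx1, a dorsal telencephalic homeobox gene, fell by 0.99 ± 0.16 (adjusted p = 0.0362), Bhlhe22 by 1.51 ± 0.25 (adjusted p = 0.0301), Plxna2, a semaphorin receptor, by 0.95 ± 0.16, Igsf8 by 0.85 ± 0.12 and Epha4, an ephrin receptor, by 0.73 ± 0.12. Prnp, the prion protein gene, rose by 0.73 ± 0.12, Phyhipl by 0.71 ± 0.12 and Dalir by 5.55 ± 0.66. The 52 G2/M phase genes moved up (median 0.14, adjusted p = 7.48e-05; adjusted p = 0.866 with an estimated correlation), with 0 members called either way, and that call was lost without E12.5 control 1 (adjusted p = 0.595) and without E12.5 cKO 2 (0.130). The median turned negative in 5 alternatives: -0.13 with at least 2000 genes per cell, -0.22 with doublets kept, -0.57 with each stage clustered on its own, -0.14 without the called genes and -0.0490 at a resolution of 1. Of 12440 genes 10 changed, 5 in each direction, and 954 had an unadjusted p under 0.05. All 10 showed no overlap, as did 10.6% of the genes tested, where chance gives 10%. The count was 0 without E12.5 control 1 or cKO 1, between 1 and 6 without E12.5 cKO 2, E12.5 control 3 or any of E14.5 control 2, control 3, cKO 2 and cKO 3, and 30 without the library labelled E12.5 control 2. With a date term it was 33, of which 9 were among the 10.

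A difference between the stage effects was called for 3 genes of intermediate progenitor-like cells, and 1350 had an unadjusted p under 0.05. Sash1 (ENSMUSG00000015305; chromosome 10, 8722219 to 8886070), a scaffold protein, differed by 1.03 ± 0.16 (adjusted p = 0.0445). The other genes, chosen after their values were seen, were Gm13889 (1.17) and Gnai1, a G protein subunit (-2.12). The count rose to 12, 18 and 9 without E12.5 control 1, E12.5 cKO 1 and E14.5 cKO 1, and was 1 without E14.5 control 1 and 0 without each other library.

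Excitatory neuron-like cells were compared in the same way. At E14.5 Cux2, a homeobox gene of upper-layer neurons (ENSMUSG00000042589; chromosome 5, 121856366 to 122050102), fell by 1.96 ± 0.17 on the log2 scale (adjusted p = 0.000138), its relative Cux1 by 0.90 ± 0.15 (adjusted p = 0.00703; 0.0502 without control 3), and the axon guidance receptor Robo2 by 1.65 ± 0.23 (adjusted p = 0.00438). Mn1 fell by 1.37 ± 0.18, Rbm24, an RNA-binding protein, by 1.59 ± 0.15, and Sorl1, a sorting receptor, by 1.55 ± 0.18. Sv2b, a synaptic vesicle glycoprotein (ENSMUSG00000053025; chromosome 7, 75114894 to 75309262), rose by 1.69 ± 0.19 (adjusted p = 0.00103) and Pcdh17, a protocadherin, by 1.30 ± 0.17 (adjusted p = 0.00265). Cluster 21 held 32.7% of cKO cells of this class on average, and clusters 5 and 4 held 31.7% and 20.7% of control cells. Cluster 38, with Eomes among its top genes, held 16.5% of cKO and 1.72% of control cells. The part of these clusters in the changes was not tested.

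Of 19 upper-layer neuron genes 5 fell and 1 rose in E14.5 excitatory neuron-like cells, 8 and 2 adjusted over the list alone (median -0.27, adjusted p = 0.000567; adjusted p = 0.733 with an estimated correlation). Of 25 neuronal migration genes 5 fell, 5 adjusted over the list alone (median -0.27, adjusted p = 6.96e-05; adjusted p = 0.733 with an estimated correlation). Of 52 G2/M phase genes 0 were called either way (median -0.27, adjusted p = 0.00191; adjusted p = 0.895 with an estimated correlation), nor were any of 42 S phase genes (median -0.16, adjusted p = 0.0259; adjusted p = 0.895 with an estimated correlation). Of 28 primary microcephaly genes Mfsd2a, a lipid transporter, fell by 1.07 ± 0.23, also adjusted over the list alone, with its call lost without any 1 of controls 1, 2 and 3 and cKO 3 and 4 (adjusted p 0.0934 to 0.150; list median -0.09, adjusted p = 0.0259; adjusted p = 0.770 with an estimated correlation). The FGF and BMP signalling list moved up (22 members, 0 called and 3 higher adjusted over the list alone; median 0.25, adjusted p = 0.0259; adjusted p = 0.819 with an estimated correlation). Without E14.5 control 1 the G2/M, S phase, microcephaly and FGF and BMP calls were lost (adjusted p = 0.166, 0.166, 0.118 and 0.166). The S phase call was also lost without cKO 2 (0.0576), and the microcephaly and FGF and BMP calls without cKO 3 (0.0847 and 0.0760) and cKO 4 (0.0515 and 0.0996). Lists not called included Wnt pathway (1 of 26 rose, Sfrp2, and 2 fell, Wnt7b by 1.14 and Sfrp1 by 0.49; 3 and 3 adjusted over the list alone; the test pointed down and the mean up). Sfrp2 was lost without any 1 of controls 1, 2 and 3 and cKO 3 and 4 (adjusted p 0.0567 to 0.110).

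Over all genes 335 of 15469 changed in E14.5 excitatory neuron-like cells, 184 higher and 151 lower. Groups of 333 did not overlap, as for 20.1% of the genes tested, where chance gives 2 of 35 arrangements. The count was 125, 80 and 85 without controls 1, 2 and 3, 139 and 184 without cKO 3 and 4, and 588 without E12.5 control 1. With a date term it was 209 (166 among the 335) and without the last date 53 (50 among them). Of 31 named genes called, 13 stayed called without any 1 library.

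At E12.5, 4 of 15469 genes changed in excitatory neuron-like cells, all higher, and 1014 had an unadjusted p under 0.05. Efnb3, an ephrin ligand (ENSMUSG00000003934; chromosome 11, 69554092 to 69560205), rose by 1.02 ± 0.15 (adjusted p = 0.0453) and Pde2a, a cyclic nucleotide phosphodiesterase, by 0.84 ± 0.11 (adjusted p = 0.0319). Ptgds and Gper1, chosen after their values were seen, rose by 2.61 ± 0.32 and 2.42 ± 0.33. All 4 showed no overlap, as did 9.03% of the genes tested, where chance gives 10%. Lists of G2/M genes (52 members, median -0.17, adjusted p = 0.0432; adjusted p = 0.938 with an estimated correlation) and interneuron genes (13 members, median 0.74, adjusted p = 0.0210; adjusted p = 0.938 with an estimated correlation) were called with 0 members called either way. The count was 0 without any 1 of E12.5 cKO 1 and 2, E14.5 control 3 and E14.5 cKO 1, 3 and 4, and was 1 without E12.5 control 1, E12.5 cKO 3 or E14.5 cKO 2. It was 2 without E12.5 control 3 or E14.5 control 1, and was 8 with a date term. The G2/M call was lost without E12.5 cKO 1 (adjusted p = 0.810), E14.5 cKO 1 (0.0512) and the library labelled E12.5 control 2 (0.679, median 0.0358). The interneuron call was lost without E12.5 control 1 (0.0871) and E12.5 cKO 2 (0.663, median -0.0180). A difference between stages was called for 1 gene, Pou3f1 (-2.15 ± 0.20, adjusted p = 0.00118), with 813 genes at an unadjusted p under 0.05. That count was 2 to 4 without E12.5 control 1, E12.5 cKO 1, E12.5 cKO 2 or E14.5 cKO 1.

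**Figure D3:**
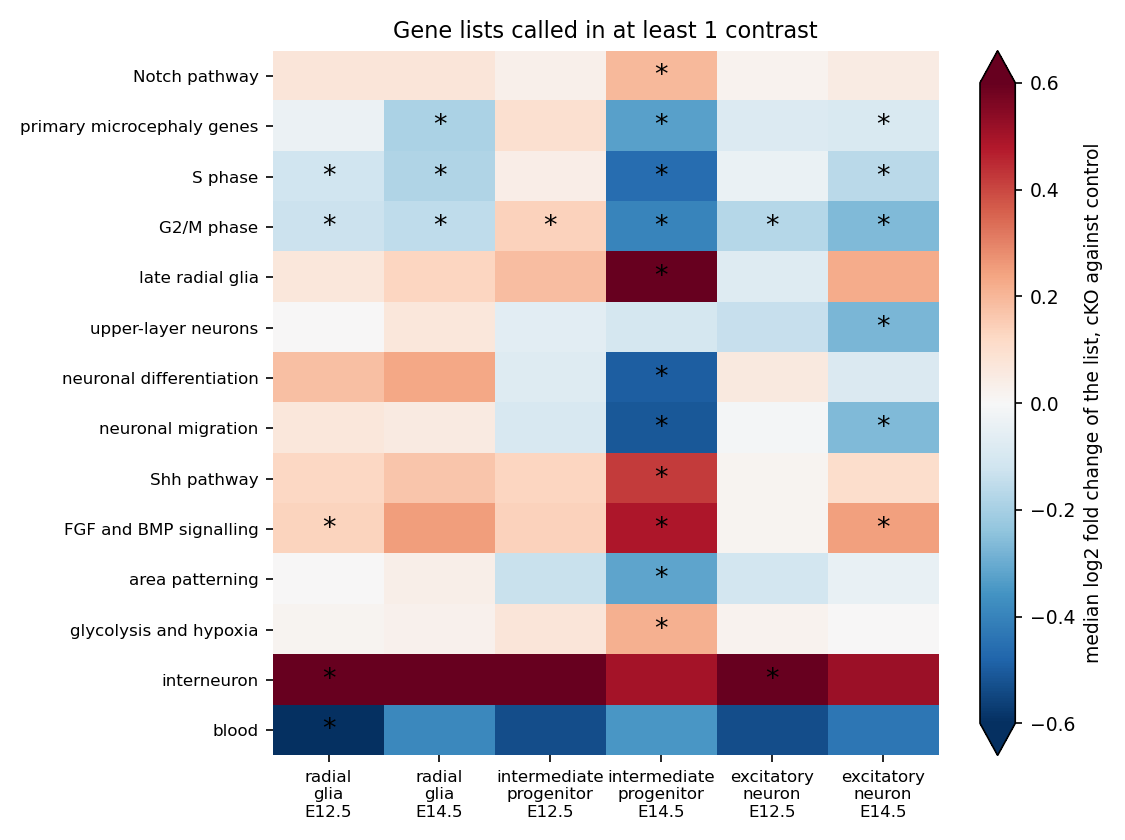
Median log2 fold change of cKO over control (colour, -0.6 to 0.6) of the 14 gene lists called at least once, in 3 cell classes at 2 stages; an asterisk marks an adjusted p under 0.05 with the preset correlation. The S phase list has its lowest median, -0.46, in E14.5 intermediate progenitor-like cells.

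As background for the genotype effects, E14.5 was compared with E12.5 in control radial glia-like cells (3 against 3, including the library labelled E12.5 control 2). Htra1, a serine protease, rose by 4.80 ± 0.82 (adjusted p = 0.00643), Bcan, the proteoglycan brevican, by 3.89 ± 0.70 and Ccdc80 by 3.84 ± 0.69. Hmga2, a chromatin protein of young progenitors, fell by 2.48 ± 0.37 (adjusted p = 0.00456), and Crabp2, a retinoic acid carrier, by 3.68 ± 0.76 (adjusted p = 0.0114; 0.0534 without E14.5 control 2 and 0.0577 without control 3). Of 8 blood genes 5 fell (median -2.20, adjusted p = 0.000356; adjusted p = 0.274 with an estimated correlation). The calls of Hba-x and Hbb-y were lost without the library labelled E12.5 control 2 (0.0591 and 0.0586), which held 317 erythroid-like cells, and without E14.5 control 2 (0.0725 and 0.0580) or control 3 (0.0879 and 0.0907). Of 24 late radial glia genes 15 rose, 18 adjusted over the list alone (median 1.12, adjusted p = 1.25e-10; adjusted p = 0.274 with an estimated correlation), and of 15 early radial glia genes 8 fell, 8 adjusted over the list alone (median -0.77, adjusted p = 2.54e-05; adjusted p = 0.274 with an estimated correlation). Of 42 S phase genes 12 fell, 15 adjusted over the list alone (median -0.18, adjusted p = 2.54e-05; adjusted p = 0.445 with an estimated correlation). Of 15466 genes 2915 changed, 1468 higher and 1447 lower. Their count was 946 and 688 without E14.5 controls 2 and 3, 796 without E12.5 control 3 and 1352 without the library labelled E12.5 control 2. With a date term it was 4456, of which 2907 were among the 2915.

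**Figure D4:**
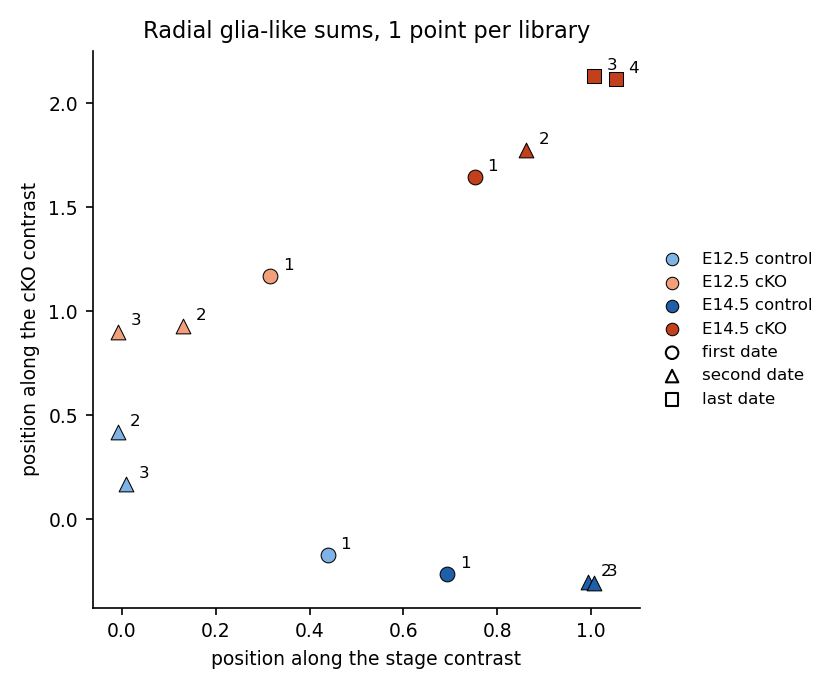
Position of each library's radial glia-like cells between E12.5 and E14.5 controls of the second date (horizontal axis, set to 0 and 1, 174 genes) and between the E12.5 controls other than the library labelled E12.5 control 2 and the E12.5 cKO libraries (vertical axis, 0 and 1, 455 genes called at E14.5), 1 point per library with the marker shape giving the date. E12.5 control 1 lies at 0.439 and E14.5 control 1 at 0.693 of the stage axis, and E14.5 cKO libraries lie at 1.65 to 2.13 of the genotype axis. The E14.5 libraries themselves selected the genes of the genotype axis, so their positions on it do not compare the sizes of the stage effects.

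The last comparison asked whether cell classes took other shares of the kept cells. Intermediate progenitor-like cells made up 11.2 ± 1.57% of E14.5 control cells (SD, n = 3) and 8.37 ± 1.26% of E14.5 cKO cells (n = 4), a difference of -2.81 (exact two-sided permutation p = 0.0286, the smallest that 35 arrangements allow; adjusted over 5 classes 0.143). At E12.5 the shares were 7.62 ± 6.37% and 2.88 ± 1.63% (n = 3 each; difference -4.73, exact p = 0.3; -1.25 without control 1 and -7.49 without the library labelled E12.5 control 2). Over both stages, with 700 arrangements, the mean difference was -3.77 (exact permutation p = 0.0343, adjusted 0.104). Interneuron-like cells, which migrate into the cortex from the subpallium, made up 2.70 ± 0.884% and 6.50 ± 2.49% at E12.5 (difference 3.81, exact p = 0.1, the smallest that 3 against 3 allows; adjusted 0.5) and 4.19 ± 0.313% and 5.12 ± 1.85% at E14.5 (exact p = 0.514). Over both stages the difference was 2.37 (exact permutation p = 0.0414, adjusted 0.104). Without E12.5 cKO 2 the E12.5 interneuron-like difference was 2.53, and the E14.5 one was 0.154 without cKO 4 and 1.65 without cKO 2. Within dates the intermediate progenitor-like difference was -9.97 and -2.12 at E12.5 and -3.47 and -0.836 at E14.5. The interneuron-like difference was 3.22, 4.10, 0.869 and -1.36. Neither class passed the correction in the exact test, while edgeR on cell counts called interneuron-like cells at E12.5 (log2 1.27, adjusted p = 0.0370). The E14.5 intermediate progenitor-like difference was 2.33 with at least 2000 genes per cell and 0.975 with doublets kept. Clusters 6 and 7, named intermediate progenitor-like, and cluster 38, named excitatory neuron-like, all had Eomes among their top genes. At E14.5 cluster 38 held 675 to 915 cells in each cKO library and 71 to 92 in each control. With at least 2000 genes per cell an Eomes cluster mostly of controls was named excitatory neuron-like. The sign of the difference thus depended on how the class was drawn. E12.5 cKO 2, with the highest interneuron-like share, also held 14.8% thalamic-like, 13.2% subpallial progenitor-like and 43.4% unnamed cells.

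Radial glia-like cells made up 34.4 ± 11.2% and 25.7 ± 15.3% at E12.5 (exact p = 0.5) and 27.7 ± 5.87% and 26.7 ± 7.23% at E14.5 (exact p = 0.886). Excitatory neuron-like cells made up 17.9 ± 11.8% and 15.6 ± 10.5% at E12.5 (exact p = 0.9) and 53.1 ± 10.2% and 55.8 ± 8.27% at E14.5 (exact p = 0.743), and their E14.5 difference within dates was 4.72 and -7.06. Cajal-Retzius-like cells, early-born neurons of the marginal zone, made up 1.83 ± 0.546% and 1.71 ± 0.496% at E12.5 (exact p = 0.7) and 1.13 ± 0.156% and 1.45 ± 0.206% at E14.5 (exact p = 0.114). The log2 ratio of intermediate progenitor-like to radial glia-like cells differed by -0.53 at E12.5 (exact p = 0.5), by -0.35 at E14.5 (exact p = 0.0571; 0.44 with at least 2000 genes per cell and -1.05 at a resolution of 1, each with exact p = 0.0286) and by -0.44 over both stages (exact p = 0.173).

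**Figure D5:**
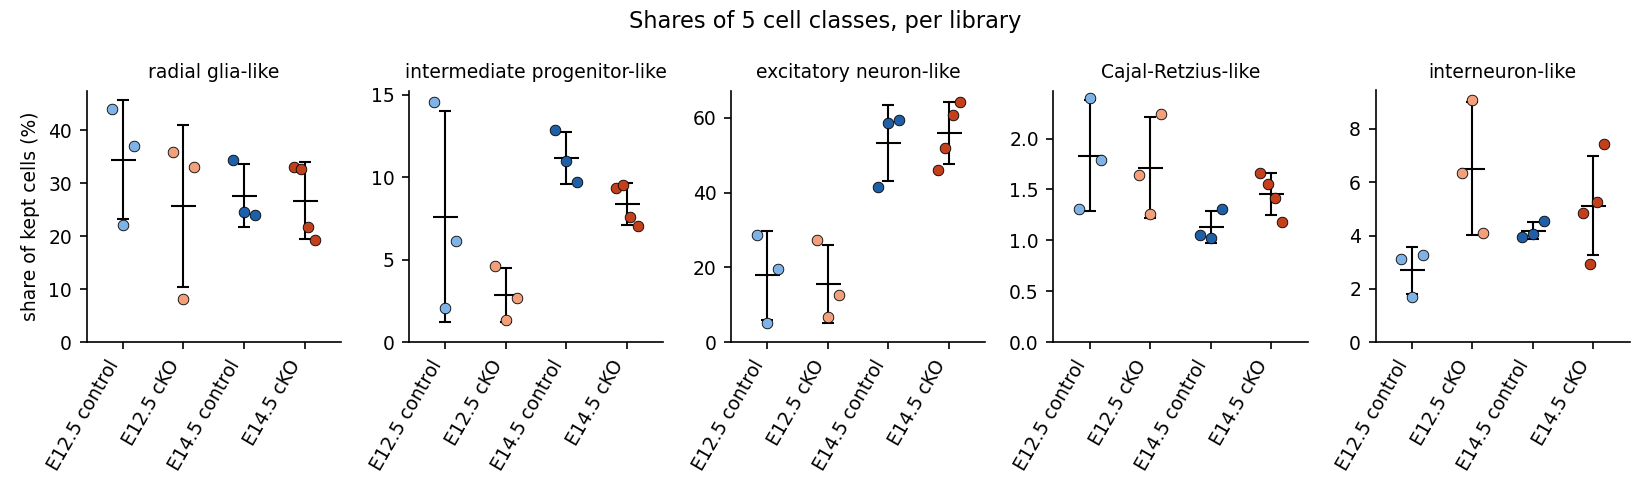
Share of kept cells (percent) in 5 cell classes, 1 point per library with the group mean and SD. E14.5 intermediate progenitor-like cells average 11.2% in controls and 8.37% in cKO libraries.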

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

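The tests of Xist and of stage position, of collection date and interneuron-like cells, and all tests of the library labelled E12.5 control 2 were chosen only after the results were seen. The per-cell mixture test and the regroupings of libraries were chosen beforehand.

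Genes called in the same direction at E14.5 in radial glia-like, intermediate progenitor-like and excitatory neuron-like cells numbered 81, 42 higher and 39 lower, among them Tet2, a DNA demethylase, and Sall4, a zinc finger factor of early progenitors. Collection date is a candidate explanation, because 2 of the 4 E14.5 cKO libraries have a date of their own. Date as a term kept 668 of the 1209 radial glia-like calls in direction and call, which argues against date as the whole cause of these calls, but excitatory neuron-like cells kept 166 of 335, and without the last date, with 2 cKO libraries left, 402 and 50 remained, so a share of date in the rest stays open. A difference shared by all cells of the cKO libraries, such as free RNA or handling, would move the same genes in interneuron-like cells. There the median change in the called direction was 0.24 (59 genes measured), against 0.84 in radial glia-like cells. The genes were selected by their calls in radial glia-like and the other cortical classes, which can raise 0.84. Interneuron-like sums come from the same libraries, so the selection can raise 0.24 as well, by an unknown amount. These medians therefore cannot decide whether a shared difference takes part. Such a difference stays open, as does a biological effect of the genotype in the cortical lineage as a hypothesis.

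Gm20646 and Dalir lay above the other controls in radial glia-like cells of the library labelled E12.5 control 2 (Gm20646 8.21 CPM), where Pou3f2 was at 0.464 CPM. Free RNA would also reach meningeal fibroblast-like cells, where Gm20646 stood at 0.0273 of its radial glia-like level. A mixture with cells of a cKO embryo at the share of 18.3% that Gm20646 needs would leave Pou3f2 at 4.16 CPM, and 0.464 CPM (interval 0.265 to 0.754) argues against it, as do 1257 of 1503 cells without Gm20646 (1313 ± 12.7 in such a mixture, 1252 at 1 rate). Along genes called at E14.5 the library lay at 0.42, with the other E12.5 controls at most at 0.17 and cKO libraries at least at 0.90. A deletion in part of the gene copies or a label other than the genotype may explain these values and stays open, untested further.

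E12.5 control 1 held 285 radial glia-like cells of clusters made mostly of E14.5 cells, and E14.5 control 1 of the same date held E12.5-type cells. Cells carried over from a first-date E14.5 library, both of which are female, would bring Xist. In the male E12.5 control 1, Xist was found in 0% of these cells (a limit of 1.05% for 3 cells), against 715 of 717 such cells in E14.5 control 1. A mixture of ages in the library would spread its cells, and the excess variance along the stage axis was -0.23 of that of a mixture. Embryos of the first date may lie nearer to each other in developmental age: E12.5 control 1 stood at 0.439 and E14.5 control 1 at 0.693 between the controls of the second date (0 and 1), and the embryos' true ages stay open.

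Libraries were also regrouped into sets of the same sizes. At E14.5, with collection date ignored, 1 of 35 regroupings, the real one, was as large in each of the 3 classes. That share is under 0.05 and the smallest that 35 regroupings allow, which argues against chance but does not exclude it. The counts were 1209 genes against at most 175 in radial glia-like cells, 1572 against 657 in intermediate progenitor-like cells and 335 against 41 in excitatory neuron-like cells. The 3 classes come from the same libraries, so these are not independent results. The highest of the others set a single cKO library, number 1, 1 and 2 in turn, with the controls. Regrouping within dates leaves 6 arrangements, too few for a share under 0.05; with date as a term the real groups gave 783, 976 and 209 genes. At E12.5 the 10 regroupings are too few for a share under 0.05. Radial glia-like cells gave 46 genes and at most 54 otherwise (2 as large), intermediate progenitor-like cells 10 and 34 (2) and excitatory neuron-like cells 4 and 16 (3). These highest regroupings put together 3 libraries of the second date: cKO 3, the library labelled E12.5 control 2 and control 3 in radial glia-like cells, and cKO 2, cKO 3 and control 3 in the others. With date as a term the real groups gave 101, 33 and 8 genes. For the stage contrast in controls 10 are likewise too few, with 2915 genes and at most 0 otherwise (1 as large).

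For differences between the stage effects chance cannot be excluded, with 4, 3 and 8 of 45 regroupings as large in radial glia-like, intermediate progenitor-like and excitatory neuron-like cells (2, 3 and 1 genes against at most 623, 481 and 398). Those highest regroupings keep the real E14.5 groups and put cKO 3, the library labelled E12.5 control 2 and control 3 of E12.5, all of the second date, together. The E14.5 difference between the real groups then enters in full, and no test separated it from a structure of the libraries. For gene lists over the 3 classes chance cannot be excluded at E14.5 (20 called, at most 25 otherwise, 6 of 35 as large), and at E12.5 10 regroupings are too few (8 called, at most 39 otherwise with cKO 2, cKO 3 and the library labelled E12.5 control 2 together, all of the second date; 9 as large).

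The CPM in this paragraph were scaled with TMM factors, so they differ slightly from those given elsewhere. In 12 of 191 groups of 4 E14.5 cKO libraries 1 library lay far from the rest, where chance at about 1 in 20 gives 9.55. In radial glia-like cells these were Wls (42.5 CPM in cKO 1, others 47.4 to 48.1), Ect2 (57.2 in cKO 4, others 51.3 to 52.1), Ttyh1 (138 in cKO 4, others 165 to 169), Fezf2 (144 in cKO 4, others 134 to 135), Sfrp1 (188 in cKO 1, others 153 to 156) and Pou3f4 (5.90 in cKO 1, others 4.84 to 5.00). In intermediate progenitor-like cells they were Pou3f1 (10.6 in cKO 4, others 13.3 to 13.8), Aurkb (36.6 in cKO 4, others 40.5 to 40.9), Neurog2 (1580 in cKO 3, others 1333 to 1348) and Epha7 (6.39 in cKO 4, others 7.20 to 7.38). In excitatory neuron-like cells they were Sphkap (14.3 in cKO 2, others 27.0 to 28.9) and Mir124-2hg (57.6 in cKO 1, others 35.2 to 37.7).

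The cKO effect differed between the stages by a test of the difference for 6 genes. In radial glia-like cells Prrx2 measured 0.03 at E12.5 and 1.55 at E14.5 (difference 1.52) and Cadm1 0.26 and 0.94 (0.68). In intermediate progenitor-like cells Gm13889 measured 0.39 and 1.56 (1.17), Sash1 0.31 and 1.34 (1.03) and Gnai1 0.22 and -1.90 (-2.12), and in excitatory neuron-like cells Pou3f1 measured -0.62 and -2.77 (-2.15).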

How the results depend on the processing

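A clustering resolution of 1 and leaving out the first or the last collection date were chosen only after the data were seen; the other alternatives were set before. Of 240 named gene results 215 were called, and 70 kept direction and side of the threshold in every alternative run, while 10 of the called ones changed direction at least once. RLE size factors left 237 of the 240 in place, DESeq2 231, no filter on low counts 222, a sex term 221, a date term 184, each stage clustered on its own 177 and leaving out the last date 146. Of the 28 list calls, 28 held with a sex term, 22 with a date term, 17 with each stage clustered on its own, 15 with doublets kept and 0 with an estimated correlation. No paired analysis was possible by replicate number because the labels give no shared replicate numbers and the numbers used here follow the deposited order. Collection date was used as a term instead. The titles of E12.5 embryos of the second date begin with D or E, each letter for a control and a cKO embryo. What these letters mean is not given in the sources used here, and pairing by them was not tested. Where a result below differs and no reason is given, the cause was not tested.

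With DESeq2 the genes changed at E12.5 were 254 in radial glia-like, 49 in intermediate progenitor-like and 64 in excitatory neuron-like cells, those at E14.5 in excitatory neuron-like cells 813, those differing between stages 50, 55 and 23, and the overlap of stages 191. Fitting only the libraries of the stage, with fewer residual degrees of freedom, gave 1, 0 and 0 genes at E12.5, 775 at E14.5 in excitatory neuron-like cells and an overlap of 1, and called Pou3f3 at 0.52 in E14.5 radial glia-like cells (adjusted p = 0.00153, range 0.00153 to 0.540). Without the filter on low counts the differences between stages were 9, 14 and 5 genes, the E12.5 intermediate progenitor-like count was 35, and Pou3f2 in E14.5 radial glia-like cells was not called (-3.86). With a sex term Pou3f2 was not called either (-3.54), and the differences between stages were 1 gene in radial glia-like and 0 in intermediate progenitor-like cells.

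With date as a term the counts were 101, 33 and 8 at E12.5 and 783, 976 and 209 at E14.5, in radial glia-like, intermediate progenitor-like and excitatory neuron-like cells in turn, 0 for the difference of stages in intermediate progenitor-like cells, 4456 for the stage contrast and 77 for the overlap, and Pou3f2 at -4.12 was not called. Without the first date they were 24, 4 and 0 at E12.5, 58, 117 and 6 for the difference of stages, 4634 for the stage contrast and 15 for the overlap. There Pou3f3 was called at 0.47 in E14.5 radial glia-like cells, and at E12.5 Pantr1 was 0.0556 in radial glia-like and 0.0350 in intermediate progenitor-like cells, Pou3f2 0.21 in intermediate progenitor-like cells and Pou3f3 -0.10 in excitatory neuron-like cells. Without the last date the E14.5 counts were 426, 650 and 53, with 2 cKO libraries left, the difference of stages was 0 in radial glia-like and in intermediate progenitor-like cells, the E12.5 excitatory neuron-like count was 0, and Pou3f2 at -3.77 was not called.

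With at least 2000 genes per cell the counts were 16, 18 and 0 at E12.5, 2619 in intermediate progenitor-like and 513 in excitatory neuron-like cells at E14.5, 1, 45 and 0 for the difference of stages and 13 for the overlap. Pou3f4 was 0.0426 in E12.5 radial glia-like cells, and the G2/M list had a median of -0.13 in E12.5 intermediate progenitor-like cells. With doublets kept the E12.5 counts were 4 in intermediate progenitor-like and 0 in excitatory neuron-like cells and the differences of stages 1, 1 and 2. The E12.5 intermediate progenitor-like G2/M median was then -0.22, Pou3f3 in E12.5 excitatory neuron-like cells was -0.00888, and in E14.5 intermediate progenitor-like cells Fgfr2 was -0.0223, the neuronal differentiation median 0.15 and the glycolysis and hypoxia median -0.10.

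With each stage clustered on its own the counts were 29 in radial glia-like and 1 in intermediate progenitor-like cells at E12.5, 0 and 6 for the difference of stages and 26 for the overlap, and Dll1 was 0.0385 in E14.5 radial glia-like cells. In E14.5 intermediate progenitor-like cells Hes5 was -0.0107, Notch2 -0.28, Hes1 -0.43, Gli3 -0.0930, Dab1 -0.00829, Fgfr2 -0.34 and Ldha -0.0252, and the medians of neuronal differentiation, Shh pathway and glycolysis and hypoxia genes were 0.34, -0.0371 and -0.12. At E12.5 Pou3f3 was -0.0404 in intermediate progenitor-like and -0.0288 in excitatory neuron-like cells, and the intermediate progenitor-like G2/M median was -0.57. Clustered without the called genes, the E12.5 counts were 18 in radial glia-like and 0 in excitatory neuron-like cells, the differences of stages 0, 0 and 3 and the overlap 16. Pou3f1 was then 0.92 in E12.5 radial glia-like cells, the E12.5 G2/M medians were 0.10 in radial glia-like and -0.14 in intermediate progenitor-like cells, and Pou3f2 at -3.73 was not called at E14.5. At a resolution of 1 the E12.5 counts were 70 in radial glia-like and 0 in excitatory neuron-like cells, and the differences of stages 0 in intermediate progenitor-like and 2 in excitatory neuron-like cells. Pou3f2 at -3.74 was not called in E14.5 radial glia-like cells, Cenpe was 0.0161 and the G2/M median 0.0171 there, the G2/M median in E12.5 intermediate progenitor-like cells was -0.0490, and Aurkb in E14.5 intermediate progenitor-like cells was 0.0131.

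Shares, as cKO minus control at E14.5 unless stated, changed direction in several alternatives, and none of these differences passed the correction over classes. Radial glia-like cells differed by 0.470 with at least 2000 genes per cell, 0.226 with doublets kept, 2.13 with each stage clustered on its own, 2.05 at a resolution of 1, 0.280 and 5.20 without the first and the last date and 3.51 within date. Excitatory neuron-like cells differed by -1.88 with at least 2000 genes, -2.92 with doublets kept, -1.85 with each stage clustered on its own, -0.000464 and -4.10 without the first and the last date, -1.17 within date and, at E12.5 as a share of 3 classes, 8.83. Intermediate progenitor-like cells differed by 2.33 with at least 2000 genes and 0.975 with doublets kept, interneuron-like cells by -0.303 without the last date and -0.245 within date, and Cajal-Retzius-like cells at E12.5 by 0.436 with each stage clustered on its own. With edgeR on cell counts interneuron-like cells were called at E12.5 (log2 1.27, adjusted p = 0.0370). The log2 ratio of intermediate progenitor-like to radial glia-like cells was 0.15 over both stages and 0.44 at E14.5 (exact p = 0.0286) with at least 2000 genes, 0.0810, 0.0368 at E12.5 and 0.13 at E14.5 with doublets kept, 0.11 and 0.46 at E12.5 with each stage clustered on its own, and -1.05 at E14.5 (exact p = 0.0286) at a resolution of 1.

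Leaving out each library in turn gave 7 to 158, 0 to 30 and 0 to 3 genes at E12.5 and 503 to 1459, 870 to 1785 and 80 to 588 at E14.5, in radial glia-like, intermediate progenitor-like and excitatory neuron-like cells. It gave 0 to 33, 0 to 18 and 1 to 4 for the difference of stages, 688 to 4192 for the stage contrast, 6 to 127 for the overlap and 25 to 39 list calls. The lowest counts followed from the loss of E12.5 cKO 1 in E12.5 radial glia-like cells, E14.5 control 2 in E14.5 radial glia-like and excitatory neuron-like cells and E14.5 control 1 in E14.5 intermediate progenitor-like cells. Pou3f2 ranged from -4.10 to -3.47 in E14.5 radial glia-like cells. At E12.5 Pantr1 ranged from -0.76 to 0.16 in radial glia-like and from -0.41 to 0.14 in excitatory neuron-like cells, Pou3f3 from -0.14 to 0.29 in intermediate progenitor-like (-0.0227 without the library labelled E12.5 control 2 and -0.0326 without control 3) and from -0.0206 to 0.24 in excitatory neuron-like cells, and Pou3f4 from -0.0719 to 0.47 in intermediate progenitor-like cells. The G2/M median ranged from -0.31 to 0.0358 in E12.5 excitatory neuron-like cells. Shares ranged from -14.9 to 0.0495 and from -3.10 to 2.39 for radial glia-like cells at E12.5 and E14.5, from -8.55 to 3.17 and from -3.22 to 5.87 for excitatory neuron-like cells, and from -0.382 to 0.165 for Cajal-Retzius-like cells at E12.5. Those of intermediate progenitor-like cells ranged from -7.49 to -1.25 and from -3.55 to -1.98, and those of interneuron-like cells from 2.53 to 5.01 and from 0.154 to 1.65. The ratio over both stages ranged from -0.65 (exact permutation p = 0.0171, without the library labelled E12.5 control 2) to -0.20.

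Intermediate progenitor-like sums held as few as 143 cells and 1.60 M UMIs. At E12.5 the test called 39 of 65 simulated 2-fold changes there and 30 of 65 in the deeper excitatory neuron-like sums. For 4-fold changes the order was the other way, with 48 of 64 and 56 of 65. The changed genes were drawn from those that passed the count filter of each class, so these shares do not measure the effect of depth.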

Other observations

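The check on free RNA was chosen only after the E14.5 results were seen, and the counts in interneuron-like and Cajal-Retzius-like cells were not planned as comparisons.

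Some genes were called in the same direction in all 3 cortical classes at E14.5. Sall4, a zinc finger factor of stem cells, fell by 6.17 ± 0.66 on the log2 scale in radial glia-like cells, by 3.68 ± 0.70 in intermediate progenitor-like cells and by 3.00 ± 0.60 in excitatory neuron-like cells. Kcnj10, an inwardly rectifying potassium channel of glia, fell by 2.95 ± 0.44, 2.31 ± 0.39 and 3.17 ± 0.54, Ahcy, which clears S-adenosylhomocysteine, by 2.29 ± 0.17, 2.17 ± 0.31 and 0.96 ± 0.19, and Tet2 by 2.03 ± 0.16, 2.42 ± 0.24 and 1.19 ± 0.10. Ptf1a, a bHLH factor of inhibitory lineages in the hindbrain and retina, rose by 3.29 ± 0.63, 4.04 ± 0.43 and 2.22 ± 0.45, and Igfbp5 by 2.89 ± 0.26, 4.86 ± 0.60 and 2.04 ± 0.45. These genes were chosen after their values were seen, apart from Igfbp5 and Tet2. In all, 316 genes were higher and 207 lower in both progenitor classes, 42 and 39 in all 3 classes, over 12336 genes tested in each class; 4 genes called in both progenitor classes went opposite ways. The classes come from the same 7 libraries, 2 of them of a date of their own, so these counts are not independent, and no value without a cKO effect was computed for them.

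Interneuron-like cells, which are born outside the cortex, showed 0 genes changed by edgeR at either stage over 11008 genes (262 and 385 at an unadjusted p under 0.05 at E12.5 and E14.5), with 1 and 6 of the gene lists called. These were the G2/M list at E12.5 (median -0.45), and at E14.5 the G2/M (-0.61), S phase (-0.41), cyclin (-0.31), microcephaly (-0.15), intermediate progenitor (-0.42) and upper-layer lists (-0.15), all lower, with adjusted p = 0.785 at E12.5 and 0.642 to 0.720 at E14.5 with an estimated correlation. In them Tet2 measured -0.09, Epha7 0.32, Ahcy 0.20 and Igfbp5 2.48 (unadjusted p = 0.00302, groups without overlap, where chance gives 2 of 35 arrangements) and Pou3f1 -2.24 (unadjusted p = 0.0354) at E14.5, none of them called (adjusted p = 0.999). Cajal-Retzius-like cells also showed 0 genes by edgeR over 10707 (385 and 337 at an unadjusted p under 0.05), with 0 and 2 lists called (p53 response and dissociation stress at E14.5, both at a median of -0.19; adjusted p = 0.282 and 0.722 with an estimated correlation) and as few as 97 cells in a library. Gm20646 stood there at 15.4 ± 4.71 CPM in E12.5 cKO libraries and at 2.53 ± 1.12 CPM in E12.5 controls (n = 3 each, including the library labelled E12.5 control 2).

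Of the radial glia identity and late radial glia lists, 12 genes were called higher in E14.5 cKO intermediate progenitor-like cells as clustered over both stages. They were picked because they rose, and list members that fell or were not called were left out. With each stage clustered on its own Hes5 (-0.0107), Hes1 (-0.43) and Gli3 (-0.0930) were not, so the rise of these depends on how the class was drawn. Free RNA from radial glia would raise such transcripts in interneuron-like cells too. Vim went from 833 to 1710 CPM in intermediate progenitor-like cells and from 113 to 65.7 CPM in interneuron-like cells. Over the 12 genes the gain in interneuron-like cells was -0.0830 to 0.118 of the gain in intermediate progenitor-like cells.

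E14.5 cKO 2 and the library labelled E12.5 control 2 shared 54 cell barcodes, where the next pair of libraries shared 33. Of 62 E12.5-type radial glia-like cells in the female E14.5 cKO 2, 22 had Xist and 1.61% had any of 4 chromosome Y genes. Of such cells in the male library labelled E12.5 control 2, 86.1% had one of these genes, so the cells without Xist do not look male. In E14.5 cKO 4, also female, 5 of 15 such cells had Xist and 0% a chromosome Y gene.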
